A study of Mus musculus with 6 samples.

How the data were processed

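Free DNA ends in sorted forebrain neurons were measured by BLISS, an assay in which the ends of double-strand breaks are repaired, tailed and joined to adaptors inside fixed nuclei, then copied by in vitro transcription and sequenced. The 6 libraries came from CK-p25 mice, whose forebrain neurons express p25, an activator of the kinase Cdk5, once doxycycline is withdrawn; all 6 are labelled with 2 weeks of induction. The titles put 2 libraries in each of 3 groups, Con, Step1 and Step2, and the labels do not say what the groups are or whether replicates are separate animals. The p-values below therefore measure only the spread between these libraries, which may be technical.

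Per the submitters' processing notes, PCR duplicates were removed by molecular identifier, reads were aligned to mm10 with Bowtie2, and alignments were converted with SAMtools and bedtools; versions are not given in the sources used here. Each line of the deposited files is 1 aligned read with its interval, strand and a score, which is the aligner's mapping quality score and ran from 11 to 42. Each read was counted at its 5′ end, taken as the labelled break end. Depth ran from 1480461 to 2403238 reads per library. Values are shares of a library's reads, so they describe where ends lay and not how many breaks a cell had.

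Reads were counted in 21755 protein-coding gene bodies of chromosomes 1 to 19 and X (GENCODE annotation of the same build), in regions from 1 kb before to 1 kb after each gene start, and in non-overlapping windows of 100 kb. Library size was the number of reads on these chromosomes outside 26 piled-up windows of 10 kb, defined as those holding over 20 times the median reads of a nonzero window (45.0). Features with at least 10 reads in at least 2 libraries were fitted with limma 3.58.1 (voom, 1 mean per group over all 6 libraries) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all features of a kind and a threshold of 0.05. Below, called means past that threshold, and errors beside log2 fold changes are standard errors of limma.

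The 17 gene lists were tested with camera in limma, with a preset correlation of 0.01 between genes and adjustment over the lists, and again with an estimated correlation. They covered recurrent-break long neural genes, early response, excitatory neuron, inhibitory neuron, synaptic, NF-kB and cytokine, interferon and antigen presentation, p53 and cell death, break repair, cohesin and chromatin architecture, ribosomal protein, histone, astrocyte, oligodendrocyte, microglia, vascular and olfactory receptor genes. Of the 46 histone symbols written, 24 matched the annotation. Shares of reads per library were compared by an exact two-sided permutation test of group means; with 2 libraries against 2 there are 6 assignments and the smallest possible p is 0.33, so this test cannot pass 0.05. Repeated positions are positions holding at least 2 reads on 1 strand after all libraries were thinned to the smallest. Intervals of single shares are 95% Wilson intervals, those of tests in the closing section exact binomial ones, and all cover counting error only.

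Groups, tests, gene lists, most alternatives and the rule for named features were fixed before the data were examined. Per comparison and direction the rule takes the 10 genes, or the 5 gene starts and 5 windows, with the largest fold change among those called, with both groups' libraries apart and a mean of at least 20 reads. Genes named only by a model number are counted and not named. Where no feature that can be named passed in a direction, the 3 with the smallest p are given as values. It also takes up to 4 members of a list with the most reads per kb, Camk2a and Cdk5r1. Some genes and regions the rule takes are not reported here. A feature named outside this rule is stated to have been chosen after its values were seen.

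Alternatives were other scalings (median of ratios, trimmed mean of M values), no or a stricter count filter, 1 read per position, a mapping quality of at least 30, limma-trend, quality weights, a replicate block, removal of a GC smooth (span 0.3), other feature sizes, 2-group fits and each library left out. In the last case the lone library of a group is assumed to vary like the other groups. Added after seeing the data were fits on each of 2 sequencing runs, which the read names showed in every library, a mapping quality of 42 only, piled-up windows left out, and 1 read per position with the GC smooth removed. The procedure was tested on simulated counts shaped like these libraries: among genes, 13.8% of changes of 1.5-fold, 46.9% of 2-fold and 93.5% of 4-fold were called, against 9.62% of 4-fold changes at gene starts and 88.1% of 2-fold changes in windows. Counting and shares used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures matplotlib 3.10.9. Chromosome Y and mitochondrial reads entered no comparison.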

Results

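Break ends were mapped in 6 BLISS libraries of sorted forebrain neurons, with 2 libraries each for Con, Step1 and Step2. The Con libraries held 2300995 and 2273508 reads, the Step1 libraries 2403238 and 2043098, and the Step2 libraries 1526487 and 1480461. Reads per distinct position were 1.29 and 1.42 in Con, 1.19 and 1.21 in Step1, and 1.24 and 1.26 in Step2. Across genes, the 2 libraries of a group correlated with r = 0.917 in Con, 0.937 in Step1 and 0.901 in Step2; genes are not independent replicates. Median read length was 49 bases in Con, 48 in Step1 and 47 in Step2, so length differed with the group.

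Most break ends lay between genes and in introns, close to the share of the genome these take up. In Con, 55.4% ± 0.696 (SD, n = 2) of reads lay between genes (58.9% of the genome), 35.6% ± 0.242 in introns (36.2%) and 3.44% ± 0.0949 in exons (3.37%). Regions within 1 kb of a gene start take up 1.60% of the genome. They held 2.80% ± 0.617 of Con reads, 2.15% ± 0.156 of Step1 reads and 2.22% ± 0.0859 of Step2 reads once piled-up windows were left out (exact permutation p = 0.33 for each group against Con). With those windows the shares were 5.5% ± 0.359, 5.55% ± 0.00446 and 5.21% ± 0.0850, because 4.09% and 3.71% of Con reads, 5.06% and 4.92% of Step1 reads and 4.41% and 4.20% of Step2 reads lay in these 26 windows. The densest of them, on chromosome 2 from 98660001 to 98670000, covers the gene models Gm10801 and Gm10800, which lie outside the naming rule and were chosen after their values were seen. It held 349545 reads over all libraries.

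The comparison of Step1 with Con asks where break ends differ between these neuron groups. Several long neural genes had fewer break ends in Step1. Rbfox1, a neuronal splicing regulator on chromosome 16 from 5885355 to 7411526, fell from 682 and 777 CPM (reads scaled to library size) in the Con libraries to 635 and 607 in Step1 (log2 fold change −0.22 ± 0.05, adjusted p = 0.0176). Pcdh9, a protocadherin, fell by 0.27 on the log2 scale (adjusted p = 0.0356). Among 40 long neural genes known as recurrent break sites in neural progenitors, 34 were lower in Step1, with a median log2 fold change of −0.10 (adjusted p = 1.63e-12 with the preset correlation and p = 0.153 with an estimated one). With median-of-ratios scaling the median was −0.06, with 29 lower. The density of break ends at gene starts was lower in both Step1 libraries than in both Con libraries.

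Of 13811 genes tested in Step1 against Con, 17 were called, 3 higher and 14 lower, and 978 had an unadjusted p below 0.05. The lower ones include short genes with changes of over 2-fold. Lsm6, an RNA-processing factor, fell by 1.64 (adjusted p = 0.0302), Mlec, a lectin of the endoplasmic reticulum, by 1.54 (adjusted p = 0.0288), Akap8l, a nuclear anchoring protein, by 1.52 (adjusted p = 0.00417), and Derl2, of endoplasmic reticulum protein degradation, by 1.43 (adjusted p = 0.0196). Of the Mlec reads, 64% lay at a single position. Hist1h1d, a linker histone on chromosome 13, fell by 1.29 (SE 0.247, adjusted p = 0.00946). Jarid2, a Polycomb cofactor, fell by 0.91 (SE 0.163, adjusted p = 0.00417), with 33.9% of its reads at a single position. Filip1l and Cmss1, which overlap on chromosome 16, fell by 0.72 and 0.59 (adjusted p = 0.00315 and 0.00379). Dlg2, Csmd1, Tenm2 and Lsamp, all long neural genes that the naming rule left out and that are named after their values were seen, fell by 0.15, 0.19, 0.21 and 0.13. The higher ones are Cma2, of the mast cell chymase family, and the 2 gene models in the densest window. Cma2 rose from 414 and 551 reads in Con to 852 and 1096 in Step1 (log2 fold change 1.04 ± 0.12, adjusted p = 2.19e-07), and 82.1% of its reads lay at a single position.

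With 1 read per position, 15 genes were called in Step1 against Con, and 5 of them were among the 17: Rbfox1, Dlg2, Csmd1, Tenm2 and Lsamp; the calls of Cma2, Lsm6, Mlec, Akap8l, Derl2, Hist1h1d, Jarid2, Filip1l, Cmss1 and Pcdh9 ended, and Gm10801 and Gm10800 turned to −0.20 and −0.22. The count was 148 without Con replicate 1, 2 without Con replicate 2, 3 and 9 without Step1 replicates 1 and 2, and 7 without either Step2 library. It was 4 within sequencing run 1 and 13 within run 2.

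In the recurrent-break list, 14 genes fell and 1 rose when adjusted over the list alone, and 4 were called over all genes tested. Examples are Rbfox1 above, Cadm2 (−0.20 ± 0.05) and Ntm (−0.13 ± 0.05), each past the threshold over the list alone; Prkg1, a kinase and the member that rose, changed by 0.17 ± 0.05. Among 40 synaptic genes, 30 were lower, with a median of −0.11 (adjusted p = 0.00198 with the preset correlation and p = 0.153 with an estimated one), and 3 fell when adjusted over the list alone: the glutamate receptor genes Grin1 (−0.83 ± 0.26) and Grm5 (−0.26 ± 0.08) and the adhesion gene Nlgn1 (−0.23 ± 0.07). The third list called, of histone genes, held 1 tested gene, Hist1h1d (adjusted p = 0.000435). With an estimated correlation none of the 3 lists was called (adjusted p = 0.153 for each). Over the 15 alternatives, adjusted p ran from 2.24e-19 to 0.153 for the recurrent-break list, from 8.68e-05 to 0.201 for the synaptic list and from 5.68e-05 to 0.551 for the histone list. The synaptic call ended without Con replicate 2 (adjusted p = 0.201, median −0.06) and within sequencing run 2 (0.0743, against 0.021 within run 1). In both runs the recurrent-break list stayed called (adjusted p = 6.88e-07 and 2.09e-06). Genes over 300 kb as a class held 12.9% ± 0.184 (SD, n = 2) of reads in Con and 12.1% ± 0.0151 in Step1 (12.7% of the genome; difference −0.781 points, and −0.802 and −0.760 within runs 1 and 2; exact permutation p = 0.33), and neither Step1 library reached either Con library.

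**Figure D1:**
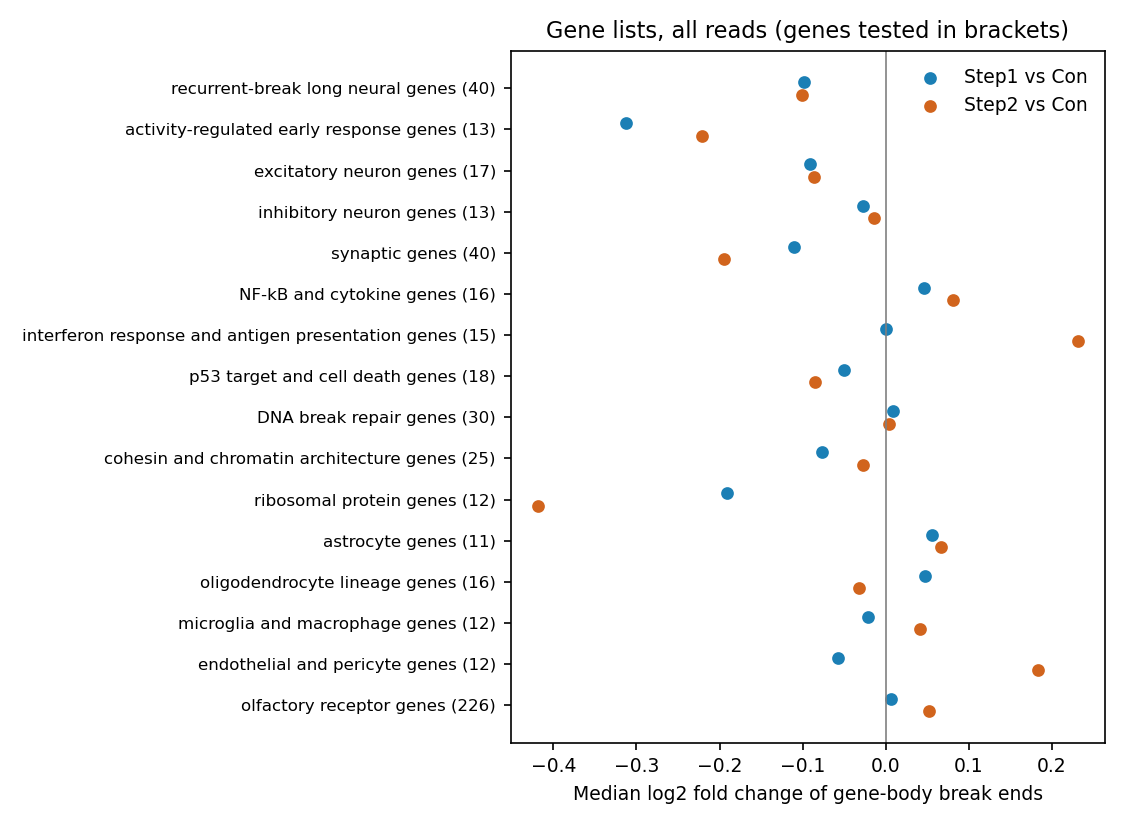
Median log2 fold change of gene-body break ends for each gene list with at least 5 tested genes, for Step1 against Con and Step2 against Con, each point 1 list and the number of tested genes in brackets. The recurrent-break and synaptic lists lie below 0 in both comparisons, at −0.10 and −0.11 for Step1 and −0.10 and −0.20 for Step2.

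Break ends peaked just upstream of gene starts in every library. The density within 200 bases of a start, relative to 4 to 5 kb away, was 2.96 and 4.80 in Con, 2.04 and 2.46 in Step1, and 1.98 and 2.31 in Step2, outside piled-up windows. With 2 libraries per group an exact permutation test cannot fall below p = 0.33. Of 917 gene-start regions with enough reads in Step1 against Con, 90.5% were lower in Step1, with a median log2 fold change of −0.95. In 63.8% the libraries of the groups did not overlap, where chance gives 33%. A shift of a whole library moves many regions together, so these regions are not independent evidence. Scaling the regions on themselves, which centres them near 0 by construction, moved the median to 0.04 by the median of ratios and 0.05 by the trimmed mean of M values. The regions that pass the count minimum are also those high in some group, which favours the group with the sharpest peak. One region was called, that of Gm10801 (0.66, named after its values were seen), and 219 had an unadjusted p below 0.05. Counting 1 read per position, 20 regions were called, all lower in Step1, and Gm10801 turned to −0.19. Without Con replicate 1 the count was 217, and without Con replicate 2 it was 9; it was 3 within sequencing run 1 and 12 within run 2. Among the regions not called and not named by a model number, the lowest p-values on the lower side belonged to Tomm40 (−1.98 ± 0.42), Lsm6 (−2.39 ± 0.55) and Mvk (−2.08 ± 0.54), and on the higher side to Gtf3c6 (2.47 ± 0.70), Trank1 (3.35 ± 1.16) and Arglu1 (1.58 ± 0.60), all with an adjusted p of 0.199 and not called.

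**Figure D2:**
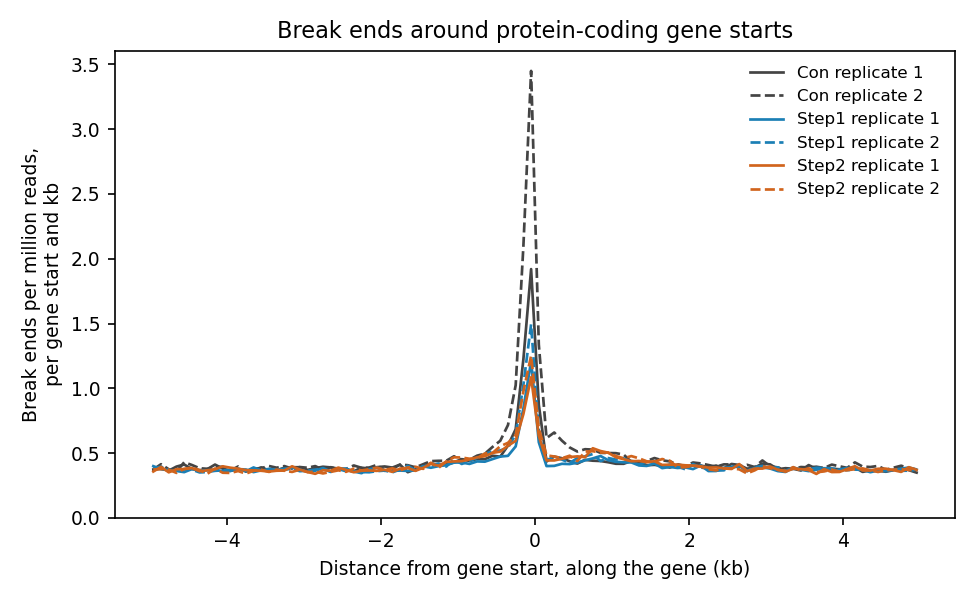
CPM of break ends per gene start and kb, in bins of 100 bases from 5 kb before to 5 kb after protein-coding gene starts, 1 line per library, outside piled-up windows. Both Con lines peak above the other 4, with ratios of 2.96 and 4.80 over the density 4 to 5 kb away, against at most 2.46 elsewhere.

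Of 25381 windows of 100 kb, 4 were called in Step1 against Con, 2 higher and 2 lower, and 1844 had an unadjusted p below 0.05. The window on chromosome 2 from 90300001, over an olfactory receptor pseudogene, rose by 3.04 ± 0.36 (adjusted p = 1.08e-09). The window on chromosome 19 from 5800001, over the noncoding RNA genes Malat1 and Neat1, fell by 1.18 (adjusted p = 0.0223), and that on chromosome 13 from 44800001, inside Jarid2, by 1.15 (adjusted p = 0.0351). With 1 read per position limma called 0 of these windows, and without piled-up windows the Malat1 value turned to 0.04. The count was 176 without Con replicate 1, 13 without Con replicate 2 and 2 without either Step2 library, and it was 3 and 2 within the 2 runs. Reads at repeated positions made up 31.8% ± 6.12 (SD, n = 2) in Con and 20.7% ± 2.94 in Step1 (exact permutation p = 0.33), with values of −8.44 and −6.82 points within the 2 runs against −11.1 over both.

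The comparison of Step2 with Con asks the same of the second neuron group. Lists of synaptic and long neural genes again lay lower. Grin1, the shared subunit of NMDA receptors on chromosome 2, fell from 67 and 65 reads to 15 and 7 (log2 fold change −2.01 ± 0.42, adjusted p = 0.025), with 41.3% of its reads at a single position. Sptbn4, a spectrin of axon initial segments, fell by 1.29 (SE 0.239, adjusted p = 0.00827). Prkce, a protein kinase C gene, Nrg3, a neuregulin, and Cadm2, an adhesion gene, fell by 0.50, 0.33 and 0.30 (adjusted p = 0.025, 0.0133 and 0.025). Among the 40 recurrent-break genes 38 were lower, with a median of −0.10 (adjusted p = 5.77e-17), and among the 40 synaptic genes 35 were lower, with a median of −0.20 (adjusted p = 1.8e-09). With an estimated correlation neither list was called (adjusted p = 0.0529 for each). With median-of-ratios scaling the recurrent-break median was −0.05, with 31 lower.

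Of 13811 genes tested in Step2 against Con, 13 were called, 2 higher and 11 lower, and 1073 had an unadjusted p below 0.05. Also lower were Hist1h1d (−1.36 ± 0.29, adjusted p = 0.0276), Jarid2 (−1.03 ± 0.19, adjusted p = 0.00827), Cma2 (−1.03 ± 0.20, adjusted p = 0.0137), Filip1l (−0.96 ± 0.15, adjusted p = 0.000447) and Cmss1 (−0.72 ± 0.12, adjusted p = 0.00193). Cntn5, an adhesion gene named after its values were seen, fell by 0.29. The higher ones were Gm10801 and Cdk8, a Mediator kinase gene on chromosome 5 from 146231230 to 146302874. Cdk8 rose from 150 and 196 reads to 256 and 396 (log2 fold change 1.5 ± 0.16, adjusted p = 7.04e-08), 43.0% of its reads lay at a single position, and with a mapping quality of at least 30 its value turned to −0.75. With 1 read per position 16 genes were called, 5 of them also with all reads: Gm10801, Prkce, Nrg3, Cadm2 and Cntn5; the calls of Cdk8, Grin1, Sptbn4, Hist1h1d, Jarid2, Cma2, Filip1l and Cmss1 ended, and those of Cdk8 and Cma2 turned to −0.18 and 0.34, and Grin1 had −1.55 (adjusted p = 0.204). The count was 106 without Con replicate 1, 7 without Con replicate 2, and 1 and 2 without Step2 replicates 1 and 2; it was 3 and 15 within sequencing runs 1 and 2.

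In the recurrent-break list 19 genes were called in Step2 against Con when adjusted over the list alone, all lower, and 2 over all genes tested. Among them were Nrg3 and Cadm2 above, Adgrb3 (−0.32 ± 0.08), an adhesion receptor gene, and Csmd3 (−0.27 ± 0.06). In the synaptic list 4 fell when adjusted over the list alone, Grin1, Grm5 (−0.30 ± 0.09), Nlgn1 (−0.28 ± 0.08) and the vesicle gene Syt1 (−0.35 ± 0.10), and 1 over all genes tested. The histone list was called on Hist1h1d alone (adjusted p = 0.00137). With an estimated correlation none of the 3 lists was called: adjusted p = 0.0529 for the recurrent-break and the synaptic list and 0.198 for the histone list. Over the 15 alternatives adjusted p ran from 7.2e-27 to 0.0529, from 1.71e-12 to 0.0529 and from 0.000194 to 0.687 for the 3 lists, and within the 2 sequencing runs it was 1.84e-08 and 1.28e-12 for the recurrent-break list and 3.57e-06 and 2.39e-06 for the synaptic list. Genes over 300 kb held 12% ± 0.0813 (SD, n = 2) of reads in Step2, −0.835 points from Con (−0.845 and −0.830 within the runs; exact permutation p = 0.33).

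At gene starts, 92.3% of the 917 regions were lower in Step2 than in Con, with a median of −1.19. The scalings that centre the regions on themselves moved this median to 0.05 and −0.01. The groups did not overlap in 72.4% of regions, against 33% by chance. A shift of a whole library moves many regions together, so they are not independent. The minimum of raw reads may also favour the deeper Con libraries (2203791 and 2183446 reads for scaling, against 1458813 and 1417749 in Step2). The share of reads within 1 kb of all gene starts, given above, was not lowest in Step2 once piled-up windows were left out. Only the Gm10801 region was called (0.42), and 190 had an unadjusted p below 0.05. Counting 1 read per position, 3 regions were called, all higher in Step2. The count was 162 without Con replicate 1, 13 without Con replicate 2, and 5 and 42 within sequencing runs 1 and 2. Among the regions not called and not named by a model number, the lowest p-values on the lower side were those of Ciart, a clock gene (−2.55 ± 0.57), Arid4a (−1.79 ± 0.43) and Kif18b (−2.30 ± 0.55), each with an adjusted p of 0.174, and on the higher side to Cst8 (4.60 ± 1.28, adjusted p = 0.184), Pcca (1.23 ± 0.56, adjusted p = 0.23) and Rexo2 (1.55 ± 0.90, adjusted p = 0.265), none of them called.

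In Step2 against Con 23 windows were called, 11 higher and 12 lower, and 2095 had an unadjusted p below 0.05. The window on chromosome 2 from 90300001 rose from 18 and 15 reads to 1865 and 2655 (log2 fold change 7.65 ± 0.35, adjusted p = 1.39e-39). Smaller rises were those over Cdk8 (1.37 ± 0.24) and in 2 windows without an annotated gene, on chromosome 11 from 109000001 (1.23 ± 0.22) and on chromosome 3 from 5800001 (1.2 ± 0.20). The Malat1 and Neat1 window fell by 1.38 (adjusted p = 9.6e-05), that of the imprinted Meg3 gene on chromosome 12 from 109500001 by 1.34 (adjusted p = 0.000281), and that of Gas5 and its small nucleolar RNAs on chromosome 1 from 161000001 by 1.23 (adjusted p = 0.000535). The Jarid2 window fell by 1.55 (adjusted p = 1.97e-05) and that of Cth and Ankrd13c on chromosome 3 from 157900001 by 1.78 (adjusted p = 3.02e-06). When each position counted as 1 read 5 windows were called, 3 of them among the 23; the Meg3 window stayed (−0.87) and the calls of the other windows named here ended. Of these the Cdk8 window turned to −0.15, that on chromosome 3 from 5800001 to −0.11 and the Jarid2 window to 0.02. The Cdk8 window also turned with a mapping quality of at least 30 (−0.62), and Jarid2 and its window with 42 only (0.14 and 0.21). The count was 153 without Con replicate 1, 10 without Con replicate 2, 15 without Step1 replicate 1, and 7 and 3 without Step2 replicates 1 and 2; it was 8 and 9 within the runs.

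Both comparisons use the same 2 Con libraries. Of the genes called in them, 4 were lower in both (Hist1h1d, Jarid2, Cmss1 and Filip1l) and 1 was higher in both (Gm10801), where the product of the counts over the genes tested gives 0.0112 and 0.000434. In 50 simulations in which no group differed but the Con libraries were shared, at most 1 lower and 1 higher gene was called in both. Every gene was simulated with the same dispersion (0.00489), while called loci varied more between libraries. Jarid2 had 145.7 and 266.1 CPM in the 2 Con libraries and Hist1h1d 41.29 and 66.41. The simulated values are therefore too low a bound for such loci. Cmss1 and Filip1l also overlap and share reads, so they are not independent in the count. Across genes the fold changes correlated with r = 0.557 against a simulated 0.443, with a covariance of 0.119 against a simulated mean of 0.0479 and maximum of 0.0506. Part of the excess over the product may come from the shared Con libraries.

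The comparison of Step2 with Step1 asks how the 2 groups differ from each other. Synaptic genes were lower in Step2: 33 of 40, with a median of −0.12 (adjusted p = 0.000881 with the preset correlation and p = 0.297 with an estimated one). The largest differences lay at a few loci. Cdk8 rose by 1.48 ± 0.16 (adjusted p = 5.93e-08) but turned to −0.645 with a mapping quality of at least 30. Cma2 fell by 2.07 (SE 0.189, adjusted p = 7.85e-10).

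Of 13811 genes, 6 were called in Step2 against Step1, 1 higher and 5 lower, and 472 had an unadjusted p below 0.05. Also lower were Drp2, a dystrophin-related gene on chromosome X (−1.35 ± 0.28, adjusted p = 0.0394), Chl1, an adhesion gene on chromosome 6 (−0.46 ± 0.07, adjusted p = 0.000477), and Gm10800 (−0.19). Of the Drp2 reads, 43.6% lay at a single position. With 1 read per position 4 genes were called, all gene models and all higher, among them Gm10800, which turned to 0.57. The fold changes of Cdk8, Cma2, Drp2 and Chl1 were then 0.05, −0.17, 0.15 and 0.13, none of them called, and Chl1 also turned with a mapping quality of 42 only (0.185). Without Step2 replicate 2 the count was 2, and within the 2 sequencing runs it was 6 and 5. In the synaptic list 0 genes were called, both adjusted over the list alone and over all genes tested; Grin1 had −1.18 ± 0.44. With an estimated correlation the synaptic list was not called (adjusted p = 0.297; from 0.000321 to 0.297 over the alternatives), and within sequencing runs 1 and 2 its adjusted p was 0.0837 and 0.00384. The recurrent-break list had 24 of 40 genes lower, with a median of −0.04 (adjusted p = 0.016), and 0 genes called by either adjustment. Its call ended with an estimated correlation (adjusted p = 0.77), with median-of-ratios scaling (0.206), within sequencing run 1 (0.722, against 0.00384 in run 2), without Step1 replicate 1 (0.127) and without Step2 replicate 1 (0.278), and over the alternatives it ran from 0.000479 to 0.77.

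At gene starts the median of the 917 regions in Step2 against Step1 was −0.25. Of these, 63.1% were lower, and in 33.2% the groups did not overlap, where chance gives 33%. The minimum of raw reads may favour the deeper Step1 libraries here. The share of reads near gene starts was lower in Step2 with all reads. With piled-up windows left out it was 0.0746 points higher in Step2, and with 1 read per position 0.182 points higher. Limma called 0 of the 917 regions, with 21 at an unadjusted p below 0.05. The count was 5 without Con replicate 1 and 6 without Con replicate 2. The lowest p-values belonged to Cst8 (1.75 ± 0.69), Rnft2 (1.37 ± 0.59) and Ivd (1.81 ± 0.79) on the higher side and Acaa2 (−1.91 ± 0.54), Gtf3c6 (−2.37 ± 0.69) and Slc2a8 (−1.90 ± 0.65) on the lower side, all with an adjusted p of 0.971. Of the windows, 11 were called, 3 higher and 8 lower, and 1090 had an unadjusted p below 0.05. The window on chromosome 2 from 90300001 rose by 4.61 ± 0.20 (adjusted p = 3.76e-43), that on chromosome 11 from 109000001 by 1.51 ± 0.22 and that of Cdk8 by 1.37 ± 0.24, though the last turned to −0.50 with a mapping quality of at least 30. The Cma2 window fell by 1.83 and the window on chromosome 3 from 108500001, which holds the small RNA gene Scarna2, by 1.39; windows without an annotated gene on chromosome 6 from 3200001 and chromosome 13 from 60200001 fell by 1.15 and 1.11. Only 2 windows were called with 1 read per position and none of the 11, and the lower windows named here turned to 0.175, 0.16, 0.23 and 0.06. The count was 4 and 7 without Step1 replicates 1 and 2, 6 and 3 without Step2 replicates 1 and 2, and 6 and 7 within the runs. Repeated positions held 30.6% ± 1.86 (SD, n = 2) of reads in Step2 (exact permutation p = 0.33 against Step1, with 9.41 and 3.45 points within the runs against 9.95 over both).

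Some of these loci owe their counts to single positions on 1 strand. More than 50% of reads lay at 1 position in 2 of the 17 genes called in Step1 against Con, 1 of the 13 in Step2 against Con and 2 of the 6 in Step2 against Step1. Position 90395133 on chromosome 2, between genes, had 1 and 0 reads in Con, 98 and 142 in Step1, and 1850 and 2643 in Step2. Position 57391611 on chromosome 16, in an intron shared by Cmss1 and Filip1l, had 109 and 243 reads in Con, 15 and 24 in Step1, and 2 and 5 in Step2. In all, 92 positions had at least 30 reads with at least 80% of the CPM in 1 group and at least 5 reads in each library of that group, 69 of them in Con, 10 in Step1 and 13 in Step2.

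**Figure D3:**
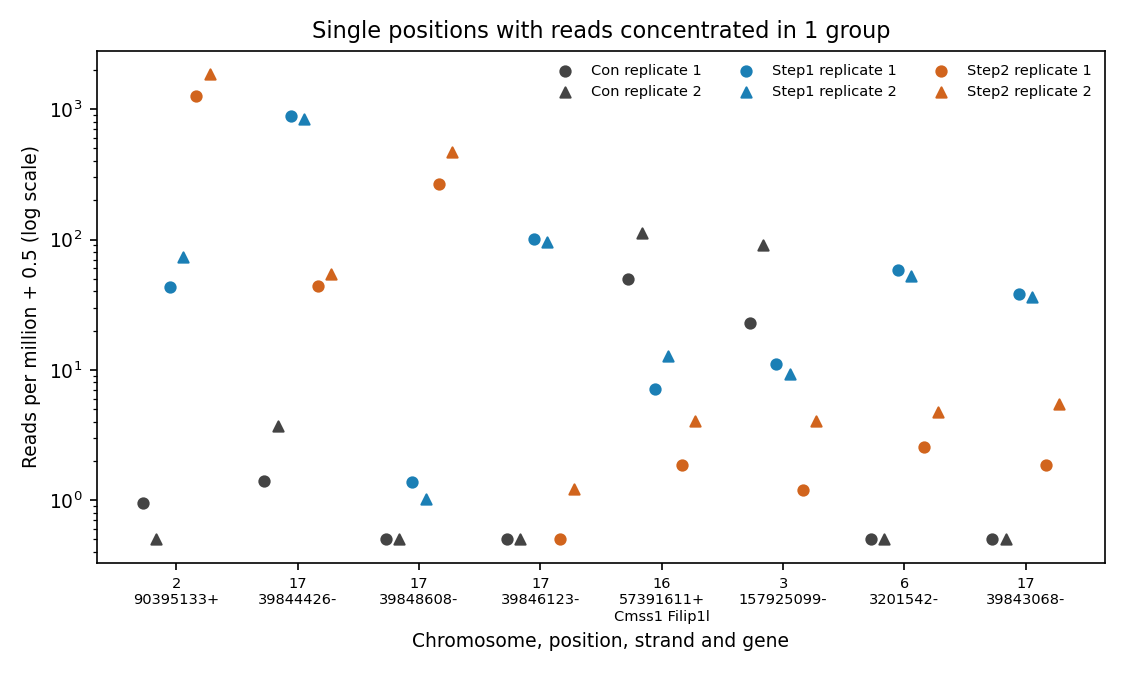
CPM plus 0.5, on a log axis, at 8 single positions with reads concentrated in 1 group, 1 point per library, coloured by group and shaped by replicate. They have the most reads among the positions reported here that have at least 50% of reads at a mapping quality of 30 or more and few reads on the opposite strand; at position 90395133 on chromosome 2 the Step2 libraries had 1850 and 2643 reads against 1 and 0 in Con.

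The other lists were not called by camera in any of the 3 comparisons. All genes tested had a median of −0.04 in both comparisons against Con, which median-of-ratios scaling removes, so small list medians depend on the scaling. Most of these medians also moved by over 1.5 times or changed sign with a single library left out. Median log2 fold changes in Step1 against Con, Step2 against Con and Step2 against Step1 were −0.31, −0.22 and 0.03 for 13 early response genes, with Fosb at −0.54 ± 0.42, −1.10 ± 0.60 and −0.57 ± 0.63. Without Con replicate 2 the early response medians against Con were −0.08 and −0.09, and without Step2 replicate 1 that of Step2 was −0.11. The medians were −0.09, −0.09 and −0.03 for 17 excitatory neuron genes, and −0.03, −0.01 and 0.00 for 13 inhibitory neuron genes, whose mean and test pointed up (means 0.06, 0.15 and 0.09). The NF-kB and cytokine genes had 0.05, 0.08 and 0.09, with a mean of −0.01 in the last, and the interferon and antigen presentation genes 0.00, 0.23 and 0.07, the second being 0.11 without Con replicate 2. For p53 target and cell death genes the medians were −0.05, −0.09 and 0.09, for break repair genes 0.01, 0.00 and 0.00, with means of −0.04, −0.06 and −0.03 and a test that pointed down in the first comparison and up in the other 2, and for cohesin and chromatin genes −0.08, −0.03 and 0.01. Ribosomal protein genes had −0.19, −0.42 and −0.36, the first being −0.02 without Step1 replicate 2 and the last −0.08 without Step2 replicate 2. Adjusted over the list alone Rpl5 fell in Step1 (−1.24 ± 0.31), and Rpl5 rose (1.06 ± 0.34) and Rpl4 fell (−0.81 ± 0.18) in Step2 against Step1, with 92.6% and 97.2% of their reads at single positions. The 226 olfactory receptor genes, silent in these neurons, had 0.01, 0.05 and 0.03, with means of −0.05 and −0.02 in the first 2.

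Markers of other cell types that a neuron sort could carry over were not called either. Medians were 0.06, 0.07 and −0.08 for astrocyte genes, 0.05, −0.03 and −0.06 for oligodendrocyte genes, −0.02, 0.04 and −0.07 for microglia genes, and −0.06, 0.18 and 0.07 for vascular genes, whose mean in the first was 0.00 and whose test pointed up. Without Con replicate 1 the vascular median in Step2 against Con was −0.03. The microglia list had a mean of 0.53 in Step1 against Con, where its test pointed up. Its 12 genes had an SD of 1.88 there, with 6 lower, 6 higher and 1 called when adjusted over the list alone. A single member can thus set the mean and the test. With 1 read per position its medians were −0.03, 0.03 and 0.06, and camera did not call it (adjusted p = 0.872, 0.659 and 0.972). Over the 15 alternatives camera called the list in 3, 1 and 4 of them, in the order of the comparisons. With either Step1 library left out it pointed upward in Step1 against Con and downward in Step2 against Step1. It was also called downward in Step2 against Step1 with a mapping quality of 42 only (adjusted p = 0.000924). Camk2a, taken by the naming rule, had log2 fold changes of −0.08 ± 0.23 in Step1 and −0.51 ± 0.28 in Step2 against Con and was not called. Cdk5r1, the gene that encodes the precursor of p25, had 3 and 5 reads in Con, 2 and 1 in Step1 and 5 and 1 in Step2, too few to test.

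By chromosome, chromosome 2 held 9.31% ± 0.286 (SD, n = 2) of reads in Con, 9.99% ± 0.156 in Step1 and 9.78% ± 0.00179 in Step2 (exact permutation p = 0.33 for each against Con). With piled-up windows left out the differences from Con were 0.0590 and 0.0441 points in place of 0.679 and 0.465. Chromosome 13 held 4.64% ± 0.0827 in Step1 and 4.39% ± 0.0365 in Step2, a difference of −0.247 points that became −0.0427 without those windows. Chromosome X held 5.85% ± 0.0646 in Con, 5.57% ± 0.0334 in Step1 and 5.56% ± 0.0344 in Step2 (exact permutation p = 0.33 for each against Con).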

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

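The fits on each sequencing run, on a mapping quality of 42 only, with piled-up windows left out, and on 1 read per position with the GC smooth removed were chosen after the data had been seen. Of 363 comparisons between a summary value and an alternative, 211 stayed the same, 150 moved and 2 reversed. Of the 45 called features named in the report, 0 stayed called in every alternative by limma; of 1015 such comparisons 675 kept the call, 299 lost it with the same direction and 41 reversed. The direction of the share in genes over 300 kb against Con held in every alternative. The cause was not tested unless stated. In the simulations gene starts had the lowest recovery and the largest dispersion (0.187 against 0.00489 for genes), and whether depth or spread limits them was not tested. Every alternative chosen before the data were examined was run.

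Leaving out 1 library at a time, the lone library of its group being assumed to vary like the other groups, gave 2 to 148, 1 to 106 and 2 to 8 genes called in Step1 against Con, Step2 against Con and Step2 against Step1. It gave 1 to 217, 1 to 162 and 0 to 6 gene starts, 2 to 176, 3 to 153 and 3 to 15 windows, and 2 to 4, 3 to 3 and 1 to 3 gene lists. Differences in share ran from −0.212 to 0.296, −0.544 to −0.0359 and −0.392 to −0.272 points for gene starts and from −0.911 to −0.651, −0.965 to −0.705 and −0.111 to 0.0036 for genes over 300 kb. For repeated positions they ran from −15.4 to −6.79, −5.49 to 3.16 and 7.87 to 12.03. For chromosome 2 they ran from 0.477 to 0.881 in Step1 and 0.263 to 0.667 in Step2 against Con, and for chromosome 13 from −0.306 to −0.189 in Step2 against Step1.

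Below, counts are of calls, in the order Step1 against Con, Step2 against Con and Step2 against Step1 unless named. Median-of-ratios scaling gave 9 genes in Step1 against Con, 6, 23 and 1 gene starts, and 1 gene list in Step2 against Step1. Trimmed mean of M values scaling gave 10 genes in Step1 against Con and 3 in Step2 against Step1, and 7, 19 and 1 gene starts. No low-count filter gave 10, 5 and 3 genes, and 3 gene starts in Step1 against Con and 3 in Step2 against Step1. At least 20 reads in 2 libraries gave 9 and 8 genes and 9 and 36 gene starts against Con. Limma-trend gave 45 genes and 14 gene starts in Step2 against Con, 10 genes in Step2 against Step1 and 14 windows in Step1 against Con. Voom with quality weights gave 30 and 25 genes against Con, 1 gene start in Step2 against Step1 and 15 windows in Step1 against Con. The GC smooth removed gave 11 genes in Step1 against Con and 5 and 4 gene starts against Con. Gene bodies with 2 kb upstream gave 29 and 32 genes against Con. Only the 2 groups compared, which leaves fewer libraries for the spread, gave 6 and 7 genes and 2 and 15 windows against Con and 3 gene starts in Step2 against Step1. Windows of 250 kb gave 7, 15 and 7 calls, and windows of 1 Mb 9 in Step2 against Con and 4 in Step2 against Step1. The estimated correlation gave 0, 0 and 0 gene lists by camera, with adjusted p from 0.0529. Genes over 100 kb changed the share differences to −1.28, −1.28 and 0.00731 points, and no thinning those of repeated positions to −7.85 in Step2 against Con and 5.32 in Step2 against Step1.

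Sequencing run 1 only gave 4 and 3 genes and 3 and 5 gene starts against Con, 8 and 6 windows in Step2 against Con and Step2 against Step1, 0 gene lists in Step2 against Step1, and gene-start differences of 0.306 points in Step1 against Con and −0.461 in Step2 against Step1. Sequencing run 2 only gave 12 and 42 gene starts against Con, 2, 9 and 7 windows, and in Step2 against Step1 −0.244 points for gene starts and 3.45 for repeated positions.

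A mapping quality of 30 or more gave 2 genes in Step2 against Step1, 2 gene starts in Step1 against Con, 14 windows in Step2 against Con and 6 in Step2 against Step1, and −0.169 points for gene starts in Step2 against Step1. In Step2 against Con and against Step1, it reversed Cdk8 to −0.75 and −0.645 and the Cdk8 window (chromosome 5 from 146200001) to −0.62 and −0.50. A mapping quality of 42 only gave 32, 24 and 2 genes, 0 and 15 gene starts against Con, and 2, 8 and 3 windows. It reversed Cdk8 to −0.76 and −0.70, its window to −0.64 and −0.58, Jarid2 and its window (chromosome 13 from 44800001) in Step2 against Con to 0.14 and 0.21, and Chl1 and the Cma2 window (chromosome 14 from 55900001) in Step2 against Step1 to 0.185 and 0.34.

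Unique break positions gave 20, 3 and 4 gene starts and 0, 5 and 2 windows. Differences in share became −0.562 points for gene starts in Step1 against Con and 0.182 in Step2 against Step1, a reversal, and −0.642 and −0.175 for genes over 300 kb in these comparisons. For chromosome 2 they became 0.0270 and 0.0349 against Con, and for chromosome 13 −0.0241 in Step2 against Step1. In Step2 against Con the reversals were Cdk8 (−0.18), Cma2 (0.34), the Cdk8 window (−0.15), the window on chromosome 3 from 5800001 (−0.11) and the Jarid2 window (0.02). In Step2 against Step1 they were Drp2 (0.15), Chl1 (0.13), the Cma2 window (0.175), the window on chromosome 3 from 108500001 (0.16) and those on chromosome 6 from 3200001 (0.23) and chromosome 13 from 60200001 (0.06). These features hold many reads per position, which the alternative counts as 1.

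Unique break positions with the GC smooth removed gave 1 and 6 genes against Con, 2, 3 and 1 gene starts, and 0, 6 and 2 windows. Reversed were, in Step2 against Con and then Step2 against Step1, Cdk8 (−0.14), Jarid2 (0.03), Cma2 (0.37), the Cdk8 window (−0.17), the window on chromosome 3 from 5800001 (−0.095) and the Jarid2 window (0.02); and Drp2 (0.12), Chl1 (0.14), the Cma2 window (0.14), and the windows on chromosome 3 from 108500001 (0.14), chromosome 6 from 3200001 (0.22) and chromosome 13 from 60200001 (0.03).

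Piled-up windows left out gave 35, 31 and 1 genes, 0 and 0 gene starts against Con by limma (the main fits hold 219 and 190 at an unadjusted p below 0.05), and 5 windows in Step2 against Step1. Gene-start differences became −0.649, −0.575 and 0.0746 points, the last a reversal, that of genes over 300 kb in Step2 against Step1 −0.147, those of chromosome 2 against Con 0.0590 and 0.0441, and that of chromosome 13 in Step2 against Step1 −0.0427. Reversed were the Malat1 window (0.042) in Step1 against Con, Cdk8 (−0.13) and its window (−0.11) in Step2 against Con, and Cdk8 (−0.078), Chl1 (0.24) and the Cma2 window (0.18) in Step2 against Step1. Leaving out the piled reads of these features is what the alternative does.

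The libraries share replicate numbers, the labels do not say whether the numbers pair them, and each comparison holds only 2 such pairs. In all 3 groups replicate 2 lay above replicate 1 on several library-wide measures. Reads from sequencing run 1 made up 43.25% and 48.75% in Con, 40.38% and 45.88% in Step1, and 43.02% and 49.89% in Step2. Reads per position and density at gene starts had the same order, so pairing is not excluded. With the replicate block the counts were 38, 43 and 11 genes, 136, 147 and 4 gene starts, and 15 and 38 windows against Con. In the pairing check, correlations of the replicate differences between groups ran from −0.0379 to 0.0668. The check correlates across features, so it cannot see a shift of a whole library.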

Other observations

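The tests of base sequence, opposite strand and exons at the piled positions, of duplicates at gene starts, and of length and GC content for the long neural genes, and the bound from the spread between libraries at gene starts, were chosen after the results had been seen, as were the genes named in the next paragraph.

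With 1 read per position, which removes the weight of single positions, limma called 15 genes in Step1 and 16 in Step2 against Con, with 14 and 12 lower. With the GC smooth removed as well the counts were 1 and 6, so most of these calls did not hold. The lower ones in Step1 included Adgrb3 (−0.26), Nrxn3 (−0.16), the calcium channel subunit gene Cacna2d3 (−0.25), Kalrn (−0.28), a regulator of dendritic spines, and Dab1 (−0.18), of reelin signalling. In Step2 they included Adgrb3 (−0.33), Kcnip4 (−0.27), Csmd3 (−0.23) and Fam155a (−0.345). Dmd, the dystrophin gene, was called in both, at −0.11 and −0.13, and so was Lrp1b, at −0.16 and −0.145.

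Mitochondrial reads made up 0.135% and 0.256% of the Con libraries, 0.0340% and 0.0425% of the Step1 libraries and 0.0202% and 0.0285% of the Step2 libraries; 81.2% to 88.5% of them lay on the minus strand. Position 5800249 on chromosome 19, antisense to Malat1, had 53 and 205 reads in Con, 7 and 18 in Step1, and 2 and 7 in Step2.

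Reads piled on single positions and strands made up the largest changes, with 7137 reads at 69 positions in Con, 17752 at 10 in Step1 and 8939 at 13 in Step2. A recurrent break with both ends captured is argued against for the set, since the opposite strand within 50 bases held a median of 0.000106 of the reads. Some positions had many opposite reads, counted over all libraries, and there this explanation stays open. They include 23556219 in Hist1h1d (76 opposite and 47 own reads), 103649226 in Chl1 (46 and 128), 109011904 on chromosome 11 (33 and 289) and 98662829 on chromosome 2 (2006 and 1839). Sharing between repeat copies present in the genome build is argued against for the set. A median of 92.5% of reads had a mapping quality of at least 30. That share was 0% at the Cdk8 position, 7.02% at 5860678 on chromosome 3, 24.1% at 60227591 on chromosome 13, 26.3% at 109011904 on chromosome 11 and 40.1% at the Malat1 position, where such sharing stays open. Copies missing from the build do not lower the mapping quality, so sharing with them was not tested. Upstream bases assigned 61.1% of 54 held-out positions to their own group (95% interval 46.9% to 74.1%), a bound that was poorly chosen because 72.2% of the positions belonged to Con; averaged over groups it was 31.5%, so adaptor or primer matches cannot be told apart from other sources. Copying from RNA also stays open. Outside piled-up windows, 29.0% of 62 positions lay in exons (95% interval 18.2% to 42%) against 4.95% of the genome, which that explanation needs. Of 18 in exons 12 were antisense (66.7%, 41.0% to 86.7%), too few to decide the strand. Exonic positions inside those windows, more of them antisense than sense, were left out of this test. Which of the group difference and library preparation produced the piles was not tested.

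Within 200 bases of gene starts and outside piled-up windows, break ends were denser in both Con libraries than in all 4 others, but the share within 1 kb did not separate Con from Step1 with all reads (5.5% and 5.55%) or Con from Step2 with 1 read per position (2.81% and 2.43%). The lowest Con library exceeded the highest other by a ratio of 1.17 with 1 read per position and of 1.07 ± 0.0115 (SE, counting error only) against bins of the same GC content. The libraries of 1 group differed by ratios of up to 1.54 and 1.32 on these measures, so the bound of counting error set in advance for GC content was too narrow, and neither duplicates nor GC content can be excluded as the source. In the first 1 kb of genes the coding strand departed from 50% by at most 2.66 percentage points in the Con libraries. It held 52.7% and 52.1% of unique positions in Con, and 52.5% to 53.2% in the other libraries. The bound set in advance applied to all positions there and not to the Con excess alone. The peak also lay just upstream of gene starts, where strand was not tested. RNA priming on 1 strand can therefore not be excluded as the source. A difference between the groups and library batches, including the difference in read length, stay open, and neither was tested.

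The recurrent-break long neural genes were lower in Step1 and Step2 than in Con. Against genes matched on length, GC content and reads, the median of the differences gene by gene was −0.0175 ± 0.0213 (SE, bootstrap over genes) in Step1. The list median less the matched median was −0.0228 ± 0.0202 there. With 1 read per position these Step1 values were −0.0213 ± 0.0161 and −0.0283 ± 0.0164. They neither show nor exclude that length or GC content suffices in Step1. In Step2 the median of the differences was −0.0601 ± 0.0198. The list median less the matched median was −0.0292 ± 0.0229, so with all reads the measure chosen decides. With 1 read per position the Step2 values were −0.0517 ± 0.0133 and −0.0397 ± 0.0162, below 0 by more than their errors. Those errors leave out the spread between libraries. With either count of reads, length or GC content therefore stays open as the whole source in Step2. With 1 Con library left out the list median lay no nearer to 0 than −0.08, which argues against that median being tied to 1 Con library. The list median includes the shift of all genes tested (−0.04) and of matched genes (−0.0752 in Step1 with all reads). The difference from matched genes was not computed with a Con library left out, so for it this question stays open. A group difference in where these neurons break and a batch difference between groups both stay open, and neither was tested.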
